A study of Mus musculus with 12 samples.

How the data were processed

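Liver RNA of 12 adult male mice was measured on 1 gene-level expression array per mouse, 6 from offspring of wild-type (WT) dams and 6 from offspring of dams lacking uncoupling protein 1 (UCP1-KO dams). Total RNA was isolated with a column kit, labelled with biotin and processed by the array maker's standard protocol, per the labels' protocols. The deposited values were log2 signals, 1 per probe set and array. They were made by the authors with robust multi-array averaging (RMA) and the Transcriptome Analysis Console, per the submitters' processing notes. RMA corrects the background of the probes, normalizes the arrays to each other and summarises the probes of a probe set on the log2 scale. The versions of these programs and the RMA variant were not given in the sources used here. Quantile normalization by the authors makes the arrays alike in their distribution of values, so a change of most genes in one direction would be reduced by it, and differences between dim probe sets are compressed on this scale.

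The 12 value columns were assigned to mice through their sample identifiers, and each group through the dam genotype in the labels. No batch, slide, scan date, litter or pairing was used, since the labels name none. The 6640 control rows (5222 negative controls, 1324 positive controls, 23 background controls and 71 spike controls) were left out of the tests. The remaining 22206 probe sets were tested with no filter on dim signals. The platform annotation gave exactly 1 gene symbol to 19572 of them and several to 0, and the other 2634 were unnamed here. All 19572 Entrez identifiers were found in a RefSeq gene table of the assembly GRCm38.p6, where 0 symbols differed. The 19505 symbols include 55 measured by more than 1 probe set. The deposited values name no genome build, so no coordinates are given. Signals are set against background by the mean of the background control probe sets, and where stated by the median of the negative controls. Precision is limited by the number of arrays.

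Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, two-sided), with the dam genotype as the only term and all 12 arrays. Differences are offspring of UCP1-KO dams minus offspring of WT dams on the log2 scale, with 95% intervals from the same fit. P-values were adjusted by the Benjamini-Hochberg method over the 22206 probe sets, and an adjusted p under 0.05 was called a change. Adjusted p-values of single genes in the text come from this limma fit. The count at an unadjusted p under 0.05 with a change of at least 1.5-fold is given beside it, as the kind of threshold the submitters' program offers. Single values per array were compared by an exact two-sided permutation test over all ways of labelling 6 of the 12 arrays, whose smallest p is 0.00217.

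The comparison, the alternatives, the genes always named and 48 gene lists (liver pathways, sex-biased and clock genes, quality markers and the cell types a liver sample could hold) were fixed before the data were examined. The text names the probe sets with 1 symbol that passed in each direction, up to 10, filled up to 5 with those of smallest p that did not pass. It also names 20 fixed genes, mostly of glucose, lipid and bile acid metabolism, of which 15 had a probe set of that symbol and 5 were not analysed here. For each list described, up to 4 members of smallest p are named. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 on 19505 genes (the brightest probe set of each), with Benjamini-Hochberg adjustment over the 47 lists tested. 1 list, of mitochondrially encoded genes, had 0 measured members. Camera with a correlation estimated per list, fry and an exact permutation test of each array's mean over the list are given beside it. Members are also counted after adjustment over the list alone.

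Both steps were tested on simulated data made from the real means and spreads. With 50 probe sets altered at each of 4 sizes among 22206, the fit recovered 18% of those altered by 0.5 log2, 80% at 1 log2 and 100% at 2 and at 3 log2. It called 157 in all, of which 8 were unaltered, and 0 had the wrong sign. The adjustment is stricter when fewer probe sets change, and the real comparison called 8 in all. The recovered shares therefore do not carry over to the real data, where differences near 1 log2 were often not called. A list raised by 0.5 log2 among 19505 genes and 47 lists was called, with 0 other lists. The simulated noise was independent between genes, whereas the 6 lists that shifted in the real data had estimated correlations of 0.24 to 0.62. The simulation therefore cannot tell how often lists of correlated genes are called falsely.

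Alternatives were quantile normalization of the deposited values, centring of each array on its median, leaving out the dimmer 50% or the dimmest 25% of probe sets, only probe sets with 1 symbol, averaging per symbol, a variance trend with robust estimation, array weights, each array left out in turn, an unequal-variance test per probe set, a looser threshold, and for lists an estimated correlation, ranks and fry. After the data were seen, 3 more were added: the median of the negative control probe sets as a covariate, leaving out WT-dam arrays 3 to 6, whose negative controls were brightest, and the exact permutation of list means. The grouping was also set against 100 of the 462 splits of the 12 arrays into equal groups, and, after the data were seen, against the 28 splits that keep WT-dam arrays 3 to 6 together.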

Results

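Liver expression was compared between adult male C57BL/6J offspring of WT dams (6 mice, arrays 1 to 6) and of UCP1-KO dams (6 mice, arrays 7 to 12). UCP1 is the protein that lets brown fat mitochondria release energy as heat. Heterozygous sires were used for both kinds of dam. The labels give all 12 offspring as heterozygous, so by these labels the groups differ in the genotype of the mother, not in their own. By this breeding the allele lacking Ucp1 came from the sire in offspring of WT dams and from the dam in those of UCP1-KO dams. That parental origin cannot be told apart from the dam genotype in any difference given below. The mice were 4 to 5 months old, ate standard chow and lived at 23 °C, and the series is concerned with how brown fat activity of the mother relates to glucose handling in her sons. The comparison therefore asks which liver transcripts differ with the dam's genotype. Because the offspring share a genotype by their labels, Ucp1 is no check of the labels here. Its probe set read 4.27 ± 0.37 (log2 signal, SD, n = 6) in offspring of WT dams and 4.10 ± 0.23 (n = 6) in offspring of UCP1-KO dams, below the background controls at 5.00 and 5.02. The labels do not say which offspring shared a dam or litter, so p-values measure the spread between these mice, some of which may be littermates.

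The arrays were alike in overall signal. Across the 22206 probe sets, which are not independent replicates, Pearson's r between arrays was 0.989 to 0.992 within the offspring of WT dams, 0.985 to 0.992 within those of UCP1-KO dams and 0.985 to 0.992 between the groups. The first principal component held 19.8% of the variance and differed in mean between the groups, at -16.3 ± 9.19 in offspring of WT dams and 16.3 ± 18.3 in offspring of UCP1-KO dams (SD, n = 6 each, exact two-sided permutation p = 0.00649). The groups overlapped on it, with WT-dam array 2 at 1.2 above UCP1-KO-dam arrays 7 and 12 at -2.4 and 0.6. UCP1-KO-dam arrays 8, 10 and 11 were highest at 37.5, 26.3 and 34.2. The median of the negative control probe sets was 6.39 ± 0.21 in the first group and 6.21 ± 0.14 in the second (n = 6 each, exact permutation p = 0.119). It was 6.41 to 6.62 on WT-dam arrays 3 to 6 and 6.14 on WT-dam arrays 1 and 2, against 5.96 to 6.36 on the arrays of the other group.

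**Figure D1:**
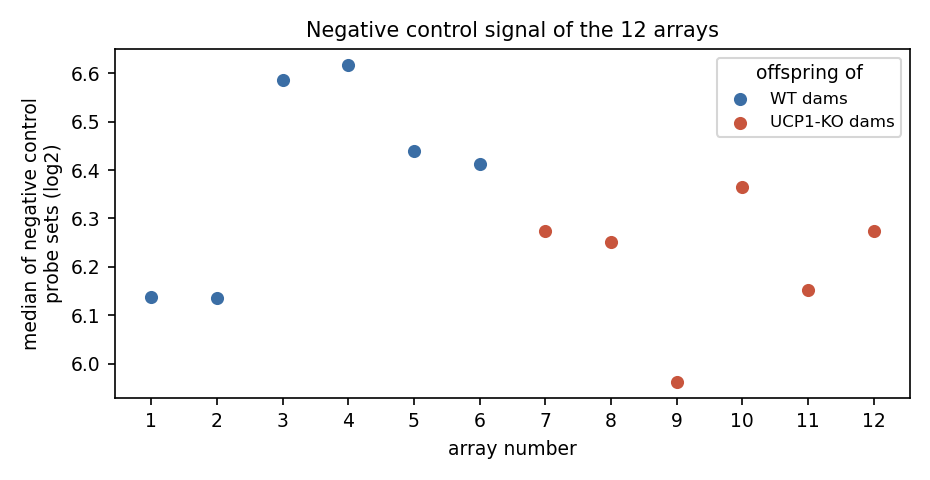
Median log2 signal of the negative control probe sets on each array, with the array number on the x axis and the dam genotype by colour. WT-dam arrays 3 to 6, at 6.41 to 6.62, lie above the other 8 arrays, which sit between 5.96 and 6.36.

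Csad, which encodes cysteine sulfinic acid decarboxylase of taurine synthesis, rose 5.40-fold in the livers of offspring of UCP1-KO dams. Its signal was 11.78 ± 1.02 (SD, n = 6) in offspring of WT dams and 14.21 ± 0.35 (n = 6) in offspring of UCP1-KO dams, a log2 difference of 2.43 (95% interval 1.70 to 3.16, limma adjusted p = 0.0139). All 6 UCP1-KO-dam arrays, at 13.88 to 14.69, lay above all 6 WT-dam arrays, at 10.82 to 13.50. It was the only named gene that passed in the upward direction. Rnf11, a RING finger protein, with a log2 difference of 0.77, and Vamp4, a vesicle fusion protein, with 0.65, did not pass (adjusted p = 0.0596 each). The predicted gene Gm3002 did not pass either (adjusted p = 0.0596). At 4.57 it lay below background in offspring of WT dams, and at 5.41 below the negative control median of 6.21 in the other group. Rpp40, a subunit of ribonuclease P, with 0.77, also did not pass (adjusted p = 0.0664). Csad lost its call in 5 of 23 alternatives: without UCP1-KO-dam array 8 (adjusted p = 0.0592), with the negative control signal as a covariate (0.0889, log2 difference 2.01), with a variance trend and robust estimation (0.0623), in the unequal-variance test per probe set (0.241) and without WT-dam arrays 3 to 6 (0.553, log2 difference 1.78).

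Lower signals in the offspring of UCP1-KO dams were called for 5 named genes. Plppr2, a phospholipid phosphatase-related membrane protein, fell by 1.32 (95% interval -1.75 to -0.90, adjusted p = 0.0232) and by 1.08 (interval -1.45 to -0.72, adjusted p = 0.0256) on the log2 scale at its 2 probe sets. Odf3b, an outer dense fibre family gene, fell by 1.53 (interval -2.04 to -1.02, adjusted p = 0.0256), from 11.08 ± 0.45 to 9.55 ± 0.55 (SD, n = 6 each), and was the 1 called gene whose groups overlapped. Polr1e, a subunit of RNA polymerase I, fell by 0.90 (interval -1.20 to -0.59, adjusted p = 0.0259), from 7.97 ± 0.18 to 7.07 ± 0.29. Mier2, a transcriptional regulator, passed (adjusted p = 0.0256) with 5.82 ± 0.34 against 4.82 ± 0.22. Sult5a1, of the sulfotransferase family, passed (adjusted p = 0.00669) with 5.07 ± 0.35 against 3.88 ± 0.07. The background controls averaged 5.00 and 5.02. Sult5a1 lay at this background in the first group and below it in the second, and Mier2 below it in the second. Against the median of the negative control probe sets, 6.39 and 6.21, the means of both genes lay lower in both groups. The size of these differences is therefore no measure of a change in transcript. For Sult5a1 expression in either group is not shown, and by the negative controls the same holds for Mier2. A further probe set without a symbol here, TC1100000916.mm.2, which lies outside the naming rule and was singled out after its values were seen, fell by 0.98 (adjusted p = 0.0139). All 7 probe sets stayed lower in every alternative in which they were measured. Except for Odf3b, whose groups overlapped, leaving out arrays could not change this. The call ended in 2 of 21 alternatives for Sult5a1, 4 of 22 for TC1100000916.mm.2, 7 and 11 of 23 for the probe sets of Plppr2, 10 of 22 for Mier2, 10 of 23 for Polr1e and 12 of 23 for Odf3b. Without WT-dam arrays 3 to 6 the differences of Plppr2 shrank to -0.78 and -0.73. Those of Odf3b (-1.10) and Sult5a1 (-0.96) also shrank, while those of Mier2 (-1.33), TC1100000916.mm.2 (-1.17) and Polr1e (-0.97) grew.

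**Figure D2:**
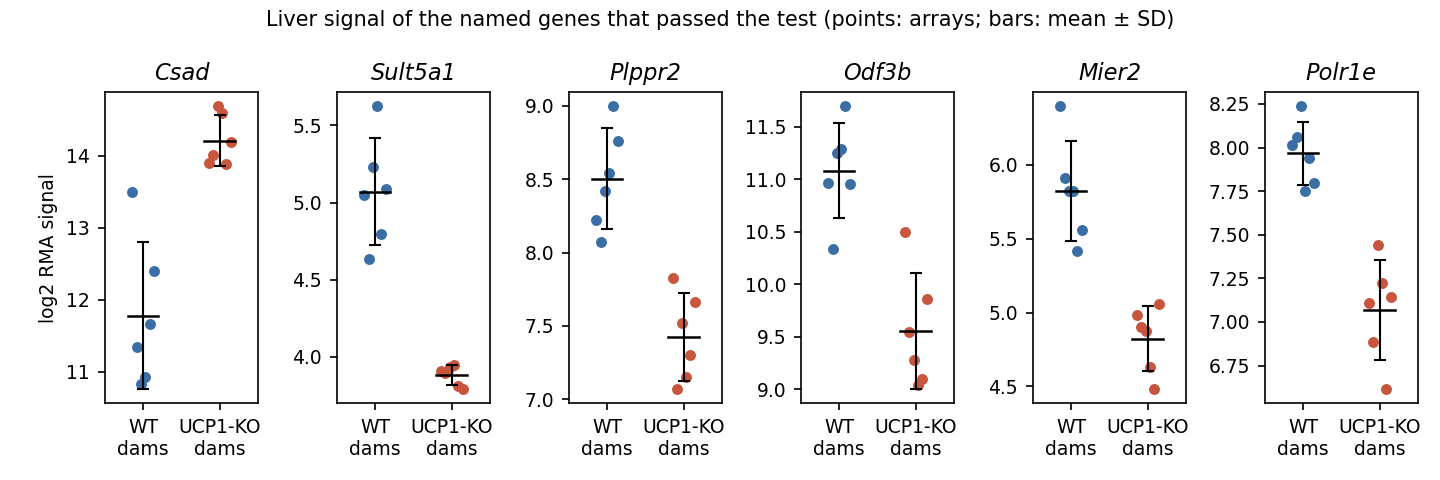
Log2 signal on each of the 12 arrays for the 6 named genes that passed the test, with points for arrays and bars for the mean ± SD of 6 arrays; each panel has its own y axis, and Plppr2 is shown by probe set TC0900000208.mm.2. Csad is higher in all 6 offspring of UCP1-KO dams (13.88 to 14.69), and the 5 other genes are lower, with overlap between the groups for Odf3b.

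In all, genes changed at 8 of the 22206 probe sets, 1 higher and 7 lower. At a looser adjusted p under 0.1, 107 passed, 38 higher and 69 lower. At an unadjusted p under 0.05 there were 2906, against 1110 by chance, and 505 of them differed by at least 1.5-fold, 147 higher and 358 lower in offspring of UCP1-KO dams. The groups did not overlap at 233 probe sets, 1.05% of those tested, where chance gives 0.216%. After quantile normalization of the deposited values the split was 3 higher and 9 lower. The count of 8 rests on single arrays: it was 112 without WT-dam array 2, 54 without UCP1-KO-dam array 7, 5 without UCP1-KO-dam array 11, 4 without UCP1-KO-dam array 9, 3 without WT-dam array 3, 2 without WT-dam array 6 and 1 without UCP1-KO-dam array 8.

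None of the 15 measured genes that were fixed for this comparison passed the test (limma adjusted p = 0.248 to 0.993), and 3 had an unadjusted p under 0.05. Apart from Ucp1, given above, they were chosen for glucose, lipid and bile acid metabolism. The 3 were Pck1, the cytosolic enzyme that commits oxaloacetate to gluconeogenesis, with 16.49 ± 0.60 against 17.07 ± 0.34 (SD, n = 6 each, log2 difference 0.58), Cpt1a, which admits long-chain fatty acids to mitochondrial oxidation, with a log2 difference of 0.39, and Cyp8b1, the sterol 12-hydroxylase of cholic acid synthesis, with -0.73 (-0.38 without UCP1-KO-dam array 9). Without WT-dam arrays 3 to 6 Pck1 had 0.26 and Cpt1a 0.22. G6pc, the liver glucose-6-phosphatase, had a log2 difference of -0.46 (95% interval -1.02 to 0.10; -0.25 without UCP1-KO-dam array 12) and the glucose transporter gene Slc2a2 -0.34 (-0.17 without UCP1-KO-dam array 10). The fatty acid receptor gene Ppara had 0.32 (0.14 without UCP1-KO-dam array 9). The fatty acid synthase gene Fasn had -0.54, with -0.29 without WT-dam array 5 and 0.20 without WT-dam arrays 3 to 6. Ppargc1a had 0.15, Irs2 0.21, Fgf21 0.17, Igfbp1 0.15, Scd1 0.05, Cyp7a1 -0.10 and Igf1 0.00. These 7 values moved by over 1.5 times with single arrays, Irs2 for example to 0.43 without WT-dam array 2 and 0.04 without UCP1-KO-dam array 11. Fgf21, at 4.62 and 4.79, was dimmer than the background controls. For Igf1 the interval was -0.25 to 0.26, while for Igfbp1 it was -1.41 to 1.70, so a change of more than 2-fold in Igfbp1 could not be excluded.

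Among genes of sugar metabolism, Pklr, the liver pyruvate kinase of glycolysis, read 14.41 ± 0.88 in offspring of WT dams and 12.35 ± 1.51 in offspring of UCP1-KO dams (SD, n = 6 each, log2 difference -2.05, 95% interval -3.21 to -0.90). It passed when adjusted over the list alone (adjusted p = 0.0309) and not over all genes (adjusted p = 0.134), as 1 of 22 measured genes of glycolysis and glycogen. The lower signals sat on UCP1-KO-dam arrays 8, 10 and 11, at 11.26, 10.77 and 10.98. Arrays 7, 9 and 12, at 13.48, 13.37 and 14.24, lay within the WT-dam range of 13.03 to 15.29. In the same list Pfkl had a log2 difference of 0.43 and Gapdh -0.38, and Ppp1r3g, at 4.03 and 4.57, lay below the background controls in both groups. Of the 15 measured gluconeogenic genes, 1 passed when adjusted over the list alone and 0 over all genes: G6pc3, the widely expressed glucose-6-phosphatase, with -1.04 (adjusted p = 0.000793 over the list alone, 0.0596 over all genes). Slc37a4, the glucose-6-phosphate transporter, had -0.42 (-0.24 without UCP1-KO-dam array 10). The lists of glycolysis (camera adjusted p = 0.424), gluconeogenesis (0.893), insulin signalling (0.671), fatty acid oxidation (0.847) and bile acids (0.898) did not shift as groups. With the negative control signal as a covariate the glycolysis list did shift lower (mean -0.23 against -0.14, which was -0.09 without UCP1-KO-dam array 10 and -0.21 without array 9, adjusted p = 0.0306), the 1 alternative of 26 in which it was called (adjusted p = 0.0306 to 0.959). The mean difference of the gluconeogenic list, 0.00, and of the bile acid list, 0.01, lay above 0 while the test pointed lower, and the insulin signalling list had a mean of -0.04 (0.04 without WT-dam array 2) and a median of 0.00. Members named by the rule were Inpp5k with -0.52, Pik3ca with 0.33, Trib1 with -0.46 and Irs1 with -0.36 (-0.13 without UCP1-KO-dam array 11) in insulin signalling, Acadl with 0.45, Hadhb with 0.34 and Cyp4a32 with -0.52 in fatty acid oxidation, and Slco1a4 with 0.66, Hsd3b7 with -0.48, Cyp2c70 with -0.47 and Cyp39a1 with 0.75 in bile acids. In each of these 3 lists 0 members passed, whether adjusted over the list alone or over all genes. Without WT-dam array 2, without UCP1-KO-dam array 7, with the dimmer probe sets left out or with a variance trend, G6pc3 passed over all genes (adjusted p = 0.0202 to 0.0488, up to 0.553 over its other alternatives).

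Lipid synthesis genes were lower on average in offspring of UCP1-KO dams. Of 25 measured lipogenic genes 19 lay below 0 (mean log2 difference -0.24, camera adjusted p = 0.0109 with the preset correlation, adjusted p = 0.959 with an estimated correlation, exact permutation p = 0.143). Mlxipl, which encodes the carbohydrate-responsive transcription factor ChREBP, had -1.04 (15.46 ± 0.61 against 14.42 ± 0.27, SD, n = 6 each) and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.00629), with 0.0891 over all genes. Thrsp, a lipogenic regulator, had -1.33, Nr1h3, the liver X receptor alpha gene, -0.42 and Acss2, an acetyl-CoA synthetase gene, -0.65 (-0.40 without UCP1-KO-dam array 8), and these did not pass. Of 19 measured cholesterol synthesis genes 16 lay below 0 (mean -0.22, camera adjusted p = 0.0196 with the preset correlation, adjusted p = 0.959 with an estimated correlation, exact permutation p = 0.320). Dhcr7, the last enzyme of the pathway to cholesterol, had -0.81, Nsdhl -0.53, Srebf2, the main transcriptional regulator of the pathway, -0.36 and Mvd -0.62 (-0.39 without WT-dam array 1), and 0 members passed, whether adjusted over the list alone or over all genes. Mlxipl passed over all genes without WT-dam array 2 (adjusted p = 0.0235), and over its alternatives the adjusted p reached 0.824. That was without WT-dam arrays 3 to 6, where the log2 difference shrank to -0.27. WT-dam arrays 1 and 2 read 14.72 and 14.66, so most of the difference sat in the 4 arrays with bright negative controls. With the covariate it was -0.65. The call of the lipogenic list ended without WT-dam array 1 (adjusted p = 0.0588), WT-dam array 5 (0.148, mean -0.15) or UCP1-KO-dam array 8 (0.0921), with the dimmer probe sets left out (0.0641) and without WT-dam arrays 3 to 6 (0.450, mean -0.13). That of the cholesterol list ended without WT-dam array 1 (0.315, mean -0.12), WT-dam array 5 (0.148), UCP1-KO-dam array 8 (0.261, mean -0.12), array 9 (0.126) or array 10 (0.0712), after quantile normalization (0.0546) and with the dimmer (0.132) or dimmest (0.0529) probe sets left out.

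Genes with zonated expression in the liver lobule differed in opposite directions. Of 15 measured pericentral hepatocyte genes, 14 lay below 0 in offspring of UCP1-KO dams (mean log2 difference -0.40, camera adjusted p = 2.5e-06 with the preset correlation, adjusted p = 0.959 with an estimated correlation), and 6 members passed when adjusted over the list alone, 0 over all genes. The members of smallest p were Lect2, a secreted hepatokine, with -0.72, and Gulo, of vitamin C synthesis, with -0.59. Next came the cytochrome P450 genes Cyp2c37 with -0.94 and Cyp2c50 with -0.67. Of 16 periportal genes, 14 lay above 0 (mean 0.31, camera adjusted p = 0.0225 with the preset correlation, adjusted p = 0.959 with an estimated correlation), and 2 passed when adjusted over the list alone, 0 over all genes: Etnppl, which breaks down phosphoethanolamine, with 0.84, and the lipid droplet protein gene Hsd17b13 with 0.45. Pck1 had 0.58 and Cyp17a1 1.46, with standard deviations of 1.29 and 2.78 for Cyp17a1, whose difference was 0.51 without UCP1-KO-dam array 11 and 0.96 without WT-dam array 6. The array means of the pericentral list were 0.20 ± 0.16 and -0.20 ± 0.37 (SD, n = 6 each, exact permutation p = 0.0390), and UCP1-KO-dam arrays 8, 10 and 11, at -0.56, -0.33 and -0.65, lay furthest below the rest. Those of the periportal list were -0.16 ± 0.21 and 0.16 ± 0.34 (n = 6 each, exact permutation p = 0.0931). Here too UCP1-KO-dam arrays 8, 10 and 11 stood apart, at 0.19, 0.28 and 0.74, while arrays 7, 9 and 12, at -0.15, 0.07 and -0.19, lay within the WT-dam range of -0.51 to 0.14. Etnppl passed over all genes without UCP1-KO-dam array 7 (adjusted p = 0.0460, up to 0.768 over its alternatives). The periportal call ended without WT-dam array 5 (0.0512), WT-dam array 6 (0.145), UCP1-KO-dam array 10 (0.0592) or array 11 (0.137, mean 0.20), with the covariate (0.166) and without WT-dam arrays 3 to 6 (0.630, mean 0.15).

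The lists of ribosomal protein and interferon response genes also shifted with the preset correlation. Under that setting 69 of 100 splits of the arrays shifted as many lists as the real grouping. Of 54 measured ribosomal protein genes 48 lay above 0 in offspring of UCP1-KO dams (mean log2 difference 0.24, camera adjusted p = 9.1e-09 with the preset correlation, adjusted p = 0.959 with an estimated correlation), and 19 passed when adjusted over the list alone, 0 over all genes. Examples were Rps4x with 0.56, Rpl7 with 0.51, Rps3a1 with 0.53 and Rps20 with 0.61. The list means per array were -0.12 ± 0.22 and 0.12 ± 0.07 (SD, n = 6 each, exact permutation p = 0.0238), and the 4 lowest arrays, WT-dam arrays 3 to 6, were those with the brightest negative controls. Without these 4 arrays the mean difference was -0.0015 and the call ended (adjusted p = 0.897). Of 31 interferon response genes 28 lay below 0 (mean -0.26, camera adjusted p = 2.1e-06 with the preset correlation, adjusted p = 0.959 with an estimated correlation, exact permutation p = 0.0758). Irf9, the DNA-binding partner of the STAT factors, with -0.51, Trim30a with -0.66, the RNA sensor gene Dhx58 with -0.73 and Xaf1 with -0.51 passed when adjusted over the list alone (4 members), and 0 passed over all genes. UCP1-KO-dam array 11 went the other way, with an interferon list mean of 0.38.

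**Figure D3:**
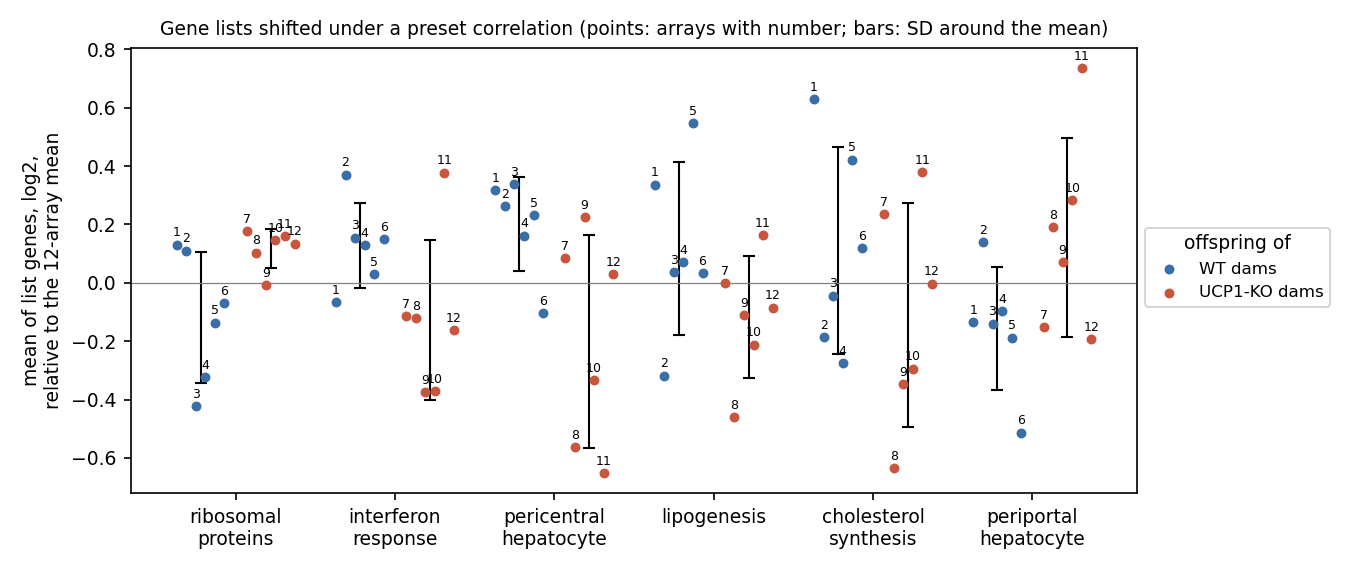
Mean over the genes of each list per array, in log2 units relative to the mean of the 12 arrays, for the 6 lists that shifted with the preset correlation; points carry their array number and bars show the SD around the mean of 6 arrays. Pericentral values are lowest on UCP1-KO-dam arrays 8, 10 and 11 (-0.56, -0.33 and -0.65), and ribosomal protein values are lowest on WT-dam arrays 3 to 6.

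Of the 47 lists tested, these 6 shifted with the preset correlation, 2 higher and 4 lower, and 0 with an estimated correlation. Fry, which tests whether a list's genes move one way, called 0 (lowest adjusted p = 0.685, 3 lists at an unadjusted p under 0.05), and its test for changes in either direction called 1, the ribosomal proteins (adjusted p = 0.0463). The exact permutation test of list means called 0 after adjustment (adjusted p = 0.788, 2 lists at an unadjusted p under 0.05). The other 41 lists had camera adjusted p-values of 0.116 to 0.991. Markers of Kupffer cells (mean log2 difference 0.05), T and NK cells (0.04), B and plasma cells (0.06), neutrophils and monocytes (0.01), stellate cells (0.10), cholangiocytes (0.04), blood (0.06), pancreas (0.08), fat (0.04), muscle (0.06) and sinusoidal endothelium (-0.04) were among these and did not shift. The Kupffer value depends on WT-dam array 2, whose list mean was 0.88, against -0.28 to -0.12 on the other WT-dam arrays. The UCP1-KO-dam arrays had -0.25 to 0.26. Of 100 splits of the 12 arrays, 69 shifted as many lists with the preset correlation.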

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

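The tests with the negative control signal as a covariate, those without WT-dam arrays 3 to 6, the splits that keep these 4 arrays together and the exact permutation tests of list means were chosen after the results they bear on were seen; the 100 splits and the single-array search were not. The single-array search covered the named genes, the lists described and the medians of the control probe sets, not all genes or lists. In these 158 groups of 6 values, 1 array stood far from the other 5 in 7, where chance gives 7.9. In offspring of UCP1-KO dams, array 9 had the lowest Cyp8b1, at 11.23 against 12.96 to 13.84, the highest Ppara, at 13.9 against 12.68 to 13.06, and the highest Cyp39a1, at 12.8 against 11.59 to 12.01. In the same group, array 12 had the lowest G6pc, at 14.41 against 15.42 to 15.89, and array 11 had the highest mean of the interferon response genes, at 0.38 against -0.38 to -0.12. In offspring of WT dams, array 2 had the highest Cyp4a32, at 14.82 against 13.87 to 14.05, and array 6 the lowest Cyp17a1, at 6.41 against 8.74 to 9.80. Outside this search, and picked after its values were seen, the Kupffer cell list had a mean of 0.88 on WT-dam array 2, against -0.28 to -0.12 on the others of its group. The count therefore does not show how unusual single arrays were beyond the values searched.

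For Csad and the 7 lower probe sets, 100 splits of the 12 arrays were drawn, the real one included. Of these, 2 called at least 8 probe sets, 4 called at least 1 in one direction and 2 at least 7 in one direction. At an unadjusted p under 0.05 and 1.5-fold, 2 gave at least 505. The highest others were 21, 17, 17 and 532, and each share lay under 0.05 for a free grouping of the arrays. Such splits treat the 12 mice as exchangeable, which shared litters would break, so chance is excluded only if the mice are independent. Of the 28 splits that keep WT-dam arrays 3 to 6 together, 3 called at least 8 (up to 46, median 0 without the real one) and 3 gave at least 505 (up to 572, median 246), so chance cannot be excluded for a grouping that holds these 4 arrays, with bright negative controls, on one side. The splits with 46 and 21 calls exchanged WT-dam array 2 for UCP1-KO-dam array 7 or 12. Leaving out WT-dam array 2 or UCP1-KO-dam array 7 alone also raised the count and kept all 8 calls. Whether single unusual arrays or a structure of the samples beside the dam genotype lies behind this was not tested. With the covariate the median size of the 8 log2 differences kept 96.3% (1.13 without it, 1.09 with it), and all 8 intervals left out 0. The median hides opposite moves. Csad (2.43, SE 0.35, to 2.01, SE 0.34), Odf3b (-1.53 to -1.30), Sult5a1 (-1.19 to -1.05) and both Plppr2 probe sets (-1.32 to -1.08 and -1.08 to -0.99) shrank. Mier2, Polr1e and TC1100000916.mm.2 grew. The intervals argue against a linear effect of that signal as the whole cause, and a partial effect stays open. Only TC1100000916.mm.2 (adjusted p = 0.0199) and Sult5a1 (0.0486), which lies at background, still passed. The other 6 reached 0.0889 to 0.135 through smaller differences or wider errors (Polr1e SE 0.15 to 0.17). Without WT-dam arrays 3 to 6 all 8 kept their direction, at 1.78 for Csad and -0.73 to -1.33 for the 7 lower probe sets. The groups did not overlap for any of the 8 except Odf3b, so leaving out arrays could not change the direction of the others. Only 2 WT-dam arrays remained, which had also helped to pick the 8. The omission therefore cannot decide whether a property of those 4 arrays was the cause. An effect of those 4 arrays, whole or partial, the dam genotype and an unlabelled litter remain open for these 8 probe sets.

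The ribosomal protein genes were higher in offspring of UCP1-KO dams by 0.24 on average. Chance stays open: 69 of 100 splits shifted at least 6 lists, up to 18, and the exact permutation of array means (p = 0.0238, adjusted p = 0.788 over the 47 lists) was run on a list picked for its shift, with 2 lists under 0.05 where chance gives 2.35. With the negative control signal as a covariate the difference kept 56.3% of its size, at 0.13 with a 95% interval of -0.06 to 0.33. WT-dam arrays 1 and 2, with negative controls as dim as those of the other group, had a list mean of 0.12, against -0.24 on WT-dam arrays 3 to 6 and 0.12 in offspring of UCP1-KO dams (difference -0.0015 without WT-dam arrays 3 to 6). RNA or array quality of those 4 arrays is therefore a candidate explanation that cannot be told apart from the dam genotype or chance, since the interval holds both 0 and the full difference.

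The pericentral hepatocyte genes were lower in offspring of UCP1-KO dams by 0.40 on average. Chance stays open here too, since the exact permutation of array means (p = 0.0390, adjusted p = 0.788 over the 47 lists) was run on a list picked for its shift. With the negative control signal as a covariate the difference kept 115.5% of its size (-0.47, 95% interval -0.90 to -0.03), which argues against that signal as the cause. The shift sits in UCP1-KO-dam arrays 8, 10 and 11, at -0.56, -0.33 and -0.65, while arrays 7, 9 and 12, at 0.09, 0.23 and 0.03, lie within the WT-dam range of -0.10 to 0.34. A change in the share of pericentral tissue in the piece of liver taken, a litter and the dam genotype also stay open and were not tested.

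Across all probe sets the group difference and the slope on the negative control signal within groups had a correlation of -0.13, and 0.227 of 1000 reassignments of that signal within the groups gave one as low. This test was fixed to count against the signal if it missed the threshold. With 6 arrays per group a share of 0.227 does not bound the size of an effect, so a contribution of that signal stays open.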

How the results depend on the processing

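The negative control covariate, the omission of WT-dam arrays 3 to 6 and the exact permutation of list means were chosen after seeing the data; the other alternatives were planned. All 8 called probe sets kept their direction under each alternative in which they were measured. For all of them except Odf3b the groups did not overlap, so the alternatives that left out arrays could not change it. The count of genes changed (8, with 1 of the genes higher and 7 of the genes lower) depended on the setting. It was 32 with the dimmer probe sets left out (6 higher, 26 lower, 6 of the 8 shared; fewer probe sets were tested), 22 with a variance trend and robust estimation (2 and 20, 7 shared), 107 at an adjusted p under 0.1 (38 and 69), 2 with the covariate (0 and 2, both shared) and 0 without WT-dam arrays 3 to 6 (0 and 0, with 1561 at an unadjusted p under 0.05 and only 2 WT-dam arrays left). The unequal-variance test per probe set gave 0 (0 and 0, lowest adjusted p 0.0610, and 0.117 to 0.241 for the 8), with 2617 at an unadjusted p under 0.05. Genes higher numbered 3 after quantile normalization and 2 with array weights. Genes at unadjusted p under 0.05 and 1.5-fold (505) were 819 without WT-dam arrays 3 to 6. The cause was not tested where none is named.

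Leaving out 1 array gave 1 to 112 genes changed, 0 to 29 genes higher and 1 to 83 genes lower. Genes changed were 112 without WT-dam array 2 (29 higher, 83 lower) and 54 without UCP1-KO-dam array 7 (15 and 39), with all 8 calls shared in both. They were 3 without WT-dam array 3 (1 and 2), 2 without WT-dam array 6 (1 and 1), 1 without UCP1-KO-dam array 8 (0 and 1), 4 without array 9 (1 and 3) and 5 without array 11 (1 and 4), 6 without WT-dam array 4 or 5 (2 and 4 in both cases), and genes higher were 2 without UCP1-KO-dam array 10.

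Leaving out WT-dam array 3 ended the calls of Plppr2, Odf3b and Mier2 (adjusted p = 0.0933) and of Polr1e (0.0986). UCP1-KO-dam array 8 ended those of Csad and TC1100000916.mm.2 (0.0592), Odf3b and Mier2 (0.0902), Plppr2 (0.0902 and 0.0926) and Polr1e (0.0926). WT-dam array 6 ended those of Plppr2 (0.0526 and 0.0668), Odf3b, Mier2 and Polr1e (0.0526) and TC1100000916.mm.2 (0.0511). The others were WT-dam array 1 for Odf3b (0.0515) and Polr1e (0.0673), array 4 for Plppr2 (TC0900000208.mm.2), Odf3b and Mier2 (0.0669), array 5 for Plppr2 (TC0900000208.mm.2) and Odf3b (0.0628) and Polr1e (0.0683), UCP1-KO-dam array 9 for Plppr2 (0.0664 for both), Odf3b (0.0738) and Mier2 (0.0690), array 10 for Plppr2 (TC0900000208.mm.2), Odf3b and Mier2 (0.0578), array 11 for these and Polr1e (0.0591), and array 12 for Polr1e (0.0553). Without WT-dam arrays 3 to 6, with only 2 WT-dam arrays left, the 8 had an adjusted p of 0.320 (Mier2) to 0.574 (Odf3b). Their log2 differences were larger there for Mier2 (-1.33), TC1100000916.mm.2 (-1.17) and Polr1e (-0.97), and smaller for the rest. Rnf11 passed in 6 alternatives (without WT-dam array 2, 0.0214, and UCP1-KO-dam array 7, 0.0376, among them), Vamp4 in 4 (0.0424 and 0.0430 without the same arrays), Gm3002 in 2 (without WT-dam array 2, 0.0423, or 4, 0.0353) and Rpp40 in 2 (0.0263 without UCP1-KO-dam array 7).

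The count of gene lists shifted (6) was 0 with a correlation estimated per list, 0 with fry and 0 by the exact permutation, and 4 to 8 with 1 array left out. Differences that were not called changed sign, that of Fasn (-0.54) being the largest of them, and so did 1 called list, the ribosomal_proteins. Igf1 was -0.041 after quantile normalization and -0.025 with centred arrays, where the gluconeogenesis (-0.026) and bile_acids (-0.020) lists also had means below 0. For these 2 lists the test pointed lower although the means were above 0 (0.0037 and 0.0093). It pointed higher, with means still above 0, after quantile normalization (bile_acids 0.023), with the dimmer probe sets left out (gluconeogenesis 0.0072, bile_acids 0.0093), with ranks (gluconeogenesis 0.0037), with fry (bile_acids 0.0093) and with the exact permutation (0.0037 and 0.0093). With the covariate Cyp7a1 was 0.33, Ucp1 0.0037, Igf1 -0.058, the fatty_acid_oxidation list -0.11 and the gluconeogenesis list -0.029. Without WT-dam arrays 3 to 6 Cyp7a1 was 0.13, Ucp1 0.087, Irs2 -0.045, Igf1 -0.15, Igfbp1 -0.26, Fasn 0.20, Scd1 -0.022, the ribosomal_proteins list -0.0015 and the fatty_acid_oxidation, gluconeogenesis and bile_acids lists -0.14, -0.081 and -0.021. With 1 array left out, the named genes and lists whose difference changed sign covered the ranges of -0.38 to 0.16 for Cyp7a1, -0.27 to 0.73 for Igfbp1, -0.043 to 0.041 for Igf1, -0.0071 to 0.090 for Scd1, -0.030 to 0.29 for Ppargc1a, -0.066 to 0.044 for the gluconeogenesis list, -0.041 to 0.12 for the fatty_acid_oxidation list, -0.11 to 0.036 for the insulin_signaling list (above 0 only without WT-dam array 2) and -0.018 to 0.030 for the bile_acids list. No paired analysis was possible because the labels name no pairing. Another background correction and a block for slide or scan date were not run, since scanner values and slides were not used here. Probe sets near the background controls, such as Sult5a1 and Mier2, have compressed differences.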

Other observations

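The genes in this and the next 2 paragraphs were picked after their values were seen, and the correlations with Dbp were fixed before Arntl was looked at. Tff3, which encodes a secreted trefoil peptide, was near background at 3.87 to 5.77 on 9 arrays and at 10.96, 10.43 and 12.23 on UCP1-KO-dam arrays 8, 10 and 11. Mmd2 followed it, at 8.80, 9.61 and 11.52 on these arrays and 4.31 to 6.33 on the others, and so did Cyp17a1, a steroid hydroxylase, at 11.32, 11.26 and 15.09 against 6.41 to 9.80. Mt1, a metallothionein, was at 14.89, 14.45 and 16.70 on these 3 arrays, at 16.16 on WT-dam array 2 and at 10.87 to 12.12 on the other 8. The 3 arrays also had the highest scores on the first principal component (37.5, 26.3 and 34.2, with 1.7 or less elsewhere). On array 11 the male-specific steroid enzyme gene Hsd3b5 was at 9.92, against 15.08 to 16.61 on the other arrays, with a mean of male-biased genes of -1.02 and of female-biased genes of 0.59. By the limma test over all mice Tff3 had a log2 difference of 3.40 between the groups (95% interval 1.02 to 5.79, adjusted p = 0.212), which did not pass.

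Of the 107 probe sets with an adjusted p under 0.1, a few that did not pass are given here as single values, with no test of a shared theme. Gcgr, the glucagon receptor gene, had a log2 difference of -0.68 (95% interval -0.96 to -0.40, adjusted p = 0.0639), without overlap of the groups. Lrg1, a secreted glycoprotein gene, had -1.02 (adjusted p = 0.0596), Shfl, an interferon-induced gene, -1.37 (0.0596) and Insig2, which restrains sterol synthesis, -0.85 (0.0891). Slc3a1, a subunit of the cystine transporter, had 1.28 (0.0948) and Gpat4, of glycerolipid synthesis, 0.78 (0.0902).

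Single members of lists that did not shift passed when adjusted over the list alone, and 0 of them over all genes. Of 20 sinusoidal endothelial genes 5 passed, Stab2 with -0.74, Plvap with -0.60, Dnase1l3 with -0.52 and Gpr182 with -0.41 lower and Lyve1 with 0.94 higher. Of 27 genes of drug metabolism 2 passed, Cyp2c54 with -1.02 and Gstm2 with -0.77. The clock gene Npas2 with -1.60, the immunoproteasome gene Psmb9 with -0.66 and the thyroxine-binding globulin gene Serpina7 with 0.85 were 1 each of their lists. So were Gzma with 0.67 at 3.87 and 4.54, below the background controls, and H2-Q5 with -0.60. H2-Q5 belonged to the quality list of substrain variants, whose mean difference was -0.01 (camera adjusted p = 0.751).

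Dbp, an output gene of the circadian clock, ranged from 10.65 to 15.70 in offspring of WT dams and from 11.07 to 15.72 in offspring of UCP1-KO dams. A hypothesis is that the mice were sampled at different points of their daily cycle. Across the 12 arrays, each value taken relative to its group mean, Dbp and Arntl, which peak at opposite times of day, had a Pearson r of -0.825 (permutation p = 0.00174, adjusted p = 0.00348) and a Spearman rho of -0.727 (permutation p = 0.0101), and r was -0.833 without the 2 arrays of most extreme Dbp. Of the 4 relations computed, Per3 had r = 0.926 (adjusted p = 4e-05; rho = 0.923, p = 6e-05), Nr1d1 r = 0.695 (adjusted p = 0.0160; rho = 0.615, p = 0.0379) and Npas2 r = -0.620 (adjusted p = 0.0327; rho = -0.657, p = 0.0235), all by permutation. Without the 2 extreme arrays r was 0.873 for Per3, 0.468 for Nr1d1 and -0.425 for Npas2, so the last 2 relations rest partly on those arrays. The values fit the hypothesis, and the labels give no time of sampling against which it could be checked.

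The genes around Ucp1 were also tested for a strain variant carried along with the knockout. Of the 200 measured genes nearest to it in the gene order of GRCm38.p6, 22 (11%) had an unadjusted p under 0.05, against 13% of the 19301 other genes (one-sided Fisher's exact p = 0.827). This decides nothing, because by the labels every offspring is heterozygous and both groups carry 1 copy of each flank. The design gives no difference in copies there to find, only one in the parent from which the flank came.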
